A study of Mus musculus with 24 samples.

How the data were processed

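The assay was low-input chromatin immunoprecipitation sequencing (ChIP-seq) of H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers. Per the labels, neuronal nuclei were sorted by FACS for the nuclear protein NeuN from the dentate gyrus of 12-week-old male C57BL/6J mice, while the sample titles name the hippocampus. Each mouse received CI-994, an inhibitor of class I histone deacetylases (HDACi, 30 mg/kg intraperitoneally), or vehicle (Veh) 1 h before the test. The mouse then went through contextual fear conditioning (CFC: 3 min of habituation followed by 2 foot shocks of 1 s at 0.2 mA) or spent as long in the same chamber without shock (Context), and was killed 1 h later. The labels list 24 samples, 12 immunoprecipitated and 12 input libraries, in 4 groups with 3 replicates of each kind. The series text describes another number of treatments and replicates than the labels, and the labels were followed. Drugs were assigned to mice at random, whereas all mice of a cage had the same conditioning protocol, so shock and cage cannot be told apart in these data.

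Per the labels' protocols, about 750000 nuclei per sample were used, chromatin was sonicated for 20 min, libraries had 14 cycles of PCR, and reads were paired-end from a NextSeq 500. The submitters' processing notes name Trimmomatic 0.38, Bowtie2 2.3.5, SAMtools 1.9, MACS2, DiffBind 2.16.2, DESeq2 1.28.1 and HOMER 4.11 with the mouse build mm10, and give neither the role of each tool nor its settings. The authors deposited whole-number counts of reads for 144154 peaks in 12 columns named by treatment and replicate. Those counts were not normalised, as far as the values show. The smallest count was 1 in every column, which 3620 cells held, so empty cells appear to have been set to 1. Column names give no antibody; since each treatment and replicate has a single column, the columns were taken as the H3K27ac libraries. Input counts were not analysed here, because no column belonged to the input samples. Per the file headers, every peak carries its width and the signed distance in base pairs to the transcription start site (TSS) of a gene. A HOMER-style annotation of its place, a ChromHMM chromatin state and a percent for that state stand beside them. The percent was deposited without a description and was not used; the state was used as given, and the chromatin map behind it is not stated.

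A peak counted as a promoter peak where its edge lay within 1000 bp of the TSS named beside it, which gave 21487 promoter peaks and 122527 other peaks among those tested. For gene lists, each gene was represented by its promoter peak with the highest mean count, giving 14154 genes. Of 18808 gene symbols in the file, 98.8% were found in a gene table of the assembly GRCm38.p6, which was used for names and for the number of protein-coding genes within 500 kb of a peak. No nearest gene was named for 428 peaks.

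Peak counts were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16. Factors came from TMM, the filter filterByExpr had a minimum count of 10, and robust estimation was on. The model had 1 term per group, and the spread of each peak was estimated from all 12 libraries together. The biological coefficient of variation had a median of 0.132 over peaks. The filter removed 140 peaks and left 144014. A peak was called at a Benjamini-Hochberg adjusted p under 0.05, and the log2 fold changes are given with their standard errors (SE). The 7 contrasts were the drug effect in CFC mice, in Context mice and over both; the shock effect in vehicle mice, in drug mice and over both; and the drug by behaviour interaction, which is the drug effect in CFC minus that in Context. Levels are in CPM, counts scaled to a library's TMM-adjusted total by edgeR. No spike-in was used here, so rises and drops are relative to the other peaks of a library.

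Gene lists were written from textbook knowledge before the data were examined, as were the main test, the rule for named peaks and the alternatives other than the last ones given below. The 22 lists held 635 distinct genes: immediate early genes, activity-regulated late response genes, glutamate receptors and postsynaptic density, presynaptic vesicle release, extracellular matrix, cell adhesion and axon guidance, cAMP, calcium and MAP kinase signalling, voltage-gated ion channels, GABA receptors, neuropeptides with growth factors and their receptors, histone deacetylases, histone acetyltransferases with acetyl readers, glucocorticoid response genes, housekeeping genes and markers of 8 cell types. The cell types were dentate gyrus granule neurons, CA pyramidal neurons, GABAergic interneurons, astrocytes, oligodendrocytes, their precursors, microglia, and endothelial and mural cells. Each list was tested against all other promoters with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The same test with an estimated correlation, and fry, which tests whether a list moves on balance in 1 direction, were run beside it. Adjusted p-values of lists were computed over the 22 lists.

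Named peaks were chosen by rule. For each contrast they were the 10 called peaks with the largest rise and the 10 with the largest drop, among those with a mean count at or above the median of tested peaks and with every library of 1 group above every library of the other. From each list, 2 to 4 members with the smallest p were taken, always with Fos, Arc, Npas4, Egr1, Nr4a1 and Bdnf for immediate early genes and Hdac1, Hdac2 and Hdac3 for deacetylases. Other promoter peaks of these genes were looked at later, and are given where named as second, other or TSS peaks. Peaks are named by the gene the file gives for them, which is the gene with the nearest TSS and need not be a regulated target. Results of some peaks and genes that the rule named are not reported here.

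Values per library (total count, share of the 1000 and 5000 highest peaks, share of promoter peaks, mean log2 level of promoter peaks minus that of other peaks, slope of log2 level on gene density, level of a satellite-like peak, and log2 level of low minus high read density) were compared with exact two-sided permutation tests, adjusted over 48 tests. With 3 libraries against 3 the smallest p such a test can reach is 0.1. Drug effects on these values were also tested by permuting drug labels within each behaviour, a test added after the data were seen. Adjusted p-values of that test, and of the difference of drug effects between behaviours, were each computed over the values listed above alone, not over the 48 tests.

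Depth ran from 6639158 to 16734757 counts per library, and the median peak had a mean of 38 counts. In simulated counts built from the means and library sizes of a subset of peaks, HDACi-CFC against Veh-CFC, edgeR recovered 15% of peaks changed 1.5-fold and 47% of peaks changed 2-fold, and called 1 of the unchanged peaks among 29894 tested. DESeq2 1.42.0 recovered 10 and 34 of the 100 peaks of each size and called 0 unchanged ones. No pair of libraries was a copy of another: over 12 pairs of replicates the scatter of counts was 1.35 to 3.22 times that of counting error. Alternatives were DESeq2, library totals only, RLE factors, loess offsets, no filter, a minimum count of 30, only the groups compared, the replicate number as a block, an adjusted p under 0.01 and leaving out each library in turn. For lists they were the estimated correlation and all peaks within 50 kb of a gene. Offsets on gene density and a covariate from the first component of the residuals were added after the data were seen. P-values measure the spread between these samples only.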

Results

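H3K27ac was profiled in NeuN-sorted nuclei of the dentate gyrus from 4 groups of mice, Veh-Context, Veh-CFC, HDACi-Context and HDACi-CFC, with 3 libraries in each. The total count in peaks ranged from 6639158 in Veh-Context replicate 2 to 16734757 in HDACi-Context replicate 2. Group means were 1.12e+07 ± 3.96e+06 counts in Veh-Context, 8.24e+06 ± 1.27e+06 in Veh-CFC, 14716379 ± 1.76e+06 in HDACi-Context and 1.22e+07 ± 2.00e+06 in HDACi-CFC (SD, n = 3). Of the 144014 peaks tested, 58.1% lay in introns and 30.2% between genes. By the chromatin state given for each peak, 29.1% were active enhancers, 23.5% primed enhancers, 10.8% strong promoters and 32.2% of a state named control.

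Mice that had been shocked differed from mice that had not in where the mark lay. The share of counts in promoter peaks was 25.5% ± 0.643 in the CFC libraries and 20.5% ± 1.67 in the Context libraries (SD, n = 6 each), higher in 6 of 6 libraries (exact permutation p = 0.0022, the smallest possible; adjusted p = 0.026). The share of the 1000 highest peaks was 13.4% ± 0.486 against 11.2% ± 0.774, with the same p. A peak at chromosome 2, 98666115 to 98667446 (mm10), lies in a stretch known to collect reads of satellite repeats, and the file names Lrrc4c, 1199123 bp away, beside it. It held 136 ± 52.2 CPM in CFC and 29.5 ± 23.9 CPM in Context libraries (SD, n = 6 each; exact permutation p = 0.0043, adjusted p = 0.030). Between drug and vehicle libraries the share in promoter peaks was 22.1% ± 3.46 and 23.8% ± 2.23 (SD, n = 6 each), which did not pass (exact permutation p = 0.34). The total count was higher with the drug, which did not pass after adjustment (exact permutation p = 0.039, adjusted p = 0.17). With drug labels permuted within each behaviour, a test added later, p was 0.025 for the promoter share, 0.01 for the total count and 0.005 for the satellite-like peak, which was lower with the drug by 53.9 CPM, with adjusted p-values of 0.05, 0.04 and 0.04 (exact permutation). The drug changed the promoter share by −0.49 percentage points in CFC and −2.89 in Context mice, a difference that did not pass (permutation p = 0.09, adjusted p = 0.19). The first principal component held 47.6% of the variance and separated the CFC from the Context libraries, while the second held 10.1% and separated drug from vehicle.

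**Figure D1:**
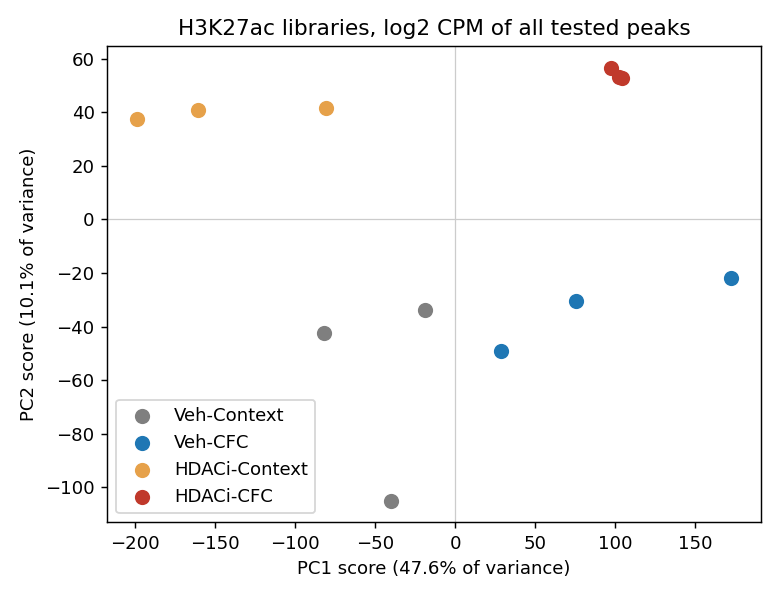
Scores of the 12 H3K27ac libraries on the first component (x axis, 47.6% of variance) and the second component (y axis, 10.1% of variance) of log2 CPM over all tested peaks. Each point is 1 library, coloured by group; the 6 CFC libraries have positive and the 6 Context libraries negative scores on the first component.

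The first comparison asked what CI-994 did in mice that received shocks, HDACi-CFC against Veh-CFC. Acetylation rose mostly at enhancers away from promoters and fell mostly at promoters. Among primed-enhancer peaks 278 rose and 20 fell, and among active-enhancer peaks 328 rose and 66 fell, while 29 strong-promoter peaks rose and 449 fell. The rises included an intronic peak of Chn1, a regulator of Rac signalling (log2 change 1.06 ± 0.18). Promoter peaks fell at Coq7 of ubiquinone synthesis (−1.499 ± 0.21), Cyp51 of cholesterol synthesis (−1.28 ± 0.22), Wdr75 of ribosome assembly (−1.30 ± 0.22) and Armcx1 of mitochondrial transport (−1.28 ± 0.20; SE, n = 3 per group). A promoter peak of the histone gene Hist1h2bb also fell (−1.22 ± 0.21), though reads may be split between near-identical histone genes. Rises spread over wider peaks than drops, with a median width of 4874 bp against 1580 bp. In all, 696 peaks rose and 626 fell by edgeR's test, of 17575 at an unadjusted p under 0.05.

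By camera with the preset correlation, promoters of signalling genes stood above other promoters in that comparison, while no list passed with an estimated correlation. Fry, which does not set a list against other promoters, called 1 of the 22 lists where camera called 6. Whether the chromatin state or width of the peaks chosen for a list accounts for the camera calls was not tested. Of 50 measured members of the cAMP, calcium and MAP kinase list, 3 rose and none fell, and 13 rose and 2 fell when adjusted over the list alone. They included the calmodulin gene Calm2 (0.79 ± 0.12). The list's median was 0.15 against −0.08 for all promoters (camera adjusted p = 9.8e-05; adjusted p = 0.16 with an estimated correlation). Of 28 immediate early genes 1 rose, Egr1 (0.47 ± 0.12), and 6 rose when adjusted over the list alone (median 0.25, adjusted p = 0.0019; adjusted p = 0.34 with an estimated correlation). Of the others in this list, Fos (0.66 ± 0.18, adjusted p = 0.062), Arc (0.31 ± 0.25), Npas4 (0.32 ± 0.12), Nr4a1 (0.35 ± 0.19) and Bdnf (0.10 ± 0.12) did not pass over all peaks, nor did Hdac1 (−0.02 ± 0.14), Hdac2 (0.36 ± 0.21) and Hdac3 (−0.31 ± 0.15) of the deacetylases. By the deposited annotation the Egr1, Arc and Npas4 peaks were intergenic active enhancers, 13713, 11831 and 7006 bp wide, that stopped short of the TSS. They counted as promoter peaks because an edge lay within 1000 bp of it. The Fos peak, intergenic, and the Nr4a1 peak, intronic, were strong promoters by state and stopped short of the TSS as well. A second promoter peak had 0.65 ± 0.20 at Egr1, 0.77 ± 0.19 at Arc (adjusted p = 0.063), 0.06 ± 0.21 at Npas4, 0.67 ± 0.32 at Nr4a1 and 0.50 ± 0.29 at Fos, and none of these passed. Late response genes (median 0.17) had 0 of 32 members past the edgeR test, also when adjusted over the list alone and 5 higher at an unadjusted p under 0.05, with camera adjusted p = 0.00065 and adjusted p = 0.19 with an estimated correlation. Extracellular matrix genes (median 0.13) likewise had 0 of 30, with 5 higher and 3 lower at an unadjusted p under 0.05 and camera adjusted p = 0.0070 and adjusted p = 0.21 with an estimated correlation. Of 41 voltage-gated channel genes 2 rose and 1 fell, 4 and 1 adjusted over the list alone (median 0.07, adjusted p = 0.0011; adjusted p = 0.19 with an estimated correlation). Of 22 glucocorticoid response genes 2 rose, 3 rose and 1 fell adjusted over the list alone (median 0.14, adjusted p = 0.0031; adjusted p = 0.33 with an estimated correlation). With all peaks within 50 kb, the matrix and glucocorticoid lists no longer passed (adjusted p = 0.13 and 0.12), and the matrix list was also lost without Veh-CFC replicate 2 (0.063).

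The microglia marker promoters had a median of −0.36 here and those of oligodendrocytes −0.14, with 0 members past the edgeR threshold in either list and 3 and 2 lower at an unadjusted p under 0.05. The count of called peaks was 409, 423 and 225 without HDACi-CFC replicates 1, 2 and 3, and 2610, 289 and 655 without Veh-CFC replicates 1, 2 and 3. Of 38 named peaks past the threshold, 12 stayed past it whichever library was left out, among them each peak given above with a gene name except Egr1, whose adjusted p was 0.035. Egr1 had an adjusted p of 0.098, 0.17 and 0.11 without HDACi-CFC replicates 1, 2 and 3, 0.19 without Veh-CFC replicates 2 or 3, 0.055 without HDACi-Context replicate 2 and 0.068 with loess offsets. The share of rises among calls moved with the scaling, from 696 and 626 to 608 rises and 890 drops with library totals and to 661 and 1034 with loess offsets, whereas DESeq2 gave 1170 and 566.

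The second comparison gave the drug effect in mice that explored the chamber without shock, HDACi-Context against Veh-Context. Here promoter peaks fell relative to other peaks on a wide front: 3912 strong-promoter peaks fell and 31 rose, and their median change was −0.39. Primed-enhancer peaks rose, with 1883 rises and 357 drops, whereas active-enhancer peaks had 564 rises and 2950 drops (median −0.09). Synaptic promoters were among the drops: Grin1, the obligatory NMDA receptor subunit (−1.32 ± 0.18), Dlg4, which encodes PSD-95 (−0.83 ± 0.12), and Slc17a7, the vesicular glutamate transporter (−1.08 ± 0.14). Immediate early promoters fell at Per1 (−0.99 ± 0.12), Junb (−1.12 ± 0.17) and Nr4a2 (−1.62 ± 0.30; SE, n = 3 per group). Rises outside promoters included an intronic peak of Deptor, an inhibitor of mTOR (1.305 ± 0.19). The promoter peak of the imprinted gene Peg3 fell as well (−2.10 ± 0.19). In all, 3928 peaks rose and 8429 fell.

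Of 45 genes of glutamate receptors and the postsynaptic density, 17 fell and 1 rose, 28 and 1 adjusted over the list alone. That list's median of −0.33 lay near the −0.31 of all promoters, and camera did not set it apart (adjusted p = 0.24). Of 28 immediate early genes 7 fell and 1 rose, 9 and 1 adjusted over the list alone, and the list's median of −0.38 lay below that of all promoters while camera's direction was up (adjusted p = 0.93). Fos rose (0.60 ± 0.19), though not by DESeq2 (adjusted p = 0.060) or without HDACi-Context replicates 2 or 3 or Veh-Context replicates 1 or 3 (adjusted p up to 0.23). Nr4a1 fell (−0.73 ± 0.20), though not without HDACi-Context replicates 2 or 3 or Veh-Context replicates 2 or 3 (adjusted p up to 0.23). Hdac3 fell (−0.999 ± 0.16, adjusted p = 2.5e-05), while Hdac1 (−0.37 ± 0.15), Hdac2 (0.39 ± 0.19), Arc (−0.44 ± 0.26), Egr1 (−0.05 ± 0.12), Npas4 (−0.15 ± 0.12) and Bdnf (0.10 ± 0.12) did not pass. The second promoter peaks of Npas4 (−0.64 ± 0.24, adjusted p = 0.082), Egr1 (−0.56 ± 0.24), Arc (−0.28 ± 0.20), Nr4a1 (−0.45 ± 0.38) and Fos (0.23 ± 0.32) did not pass either.

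The list that camera called was again cAMP, calcium and MAP kinase signalling, less lowered than other promoters: its median was −0.07, and 4 of 50 rose and 9 fell, 6 and 12 adjusted over the list alone (adjusted p = 0.020; adjusted p = 0.73 with an estimated correlation). Microglia markers had a median of −0.61, with 5 of 12 lower (5 adjusted over the list alone), and oligodendrocyte markers −0.55, with 5 of 15 lower (8). Outside promoters, peaks named for oligodendrocyte markers had a median of −0.38 (0 of 133 higher, 16 lower). Those of their precursors had −0.45 (1 of 36 higher, 6 lower). In the other cell type lists this median ran from −0.20 (microglia) to 0.06 (granule neurons). A difference in oligodendrocyte nuclei between these groups was not tested. The call of the signalling list was lost without Veh-Context replicate 1 (adjusted p = 0.062) or HDACi-Context replicate 1 (0.099). The peak count was 4630 without Veh-Context replicate 3, and 17531, 5820 and 6786 without HDACi-Context replicates 1, 2 and 3 (17531 lying within 1.5 times the full count), and with library totals it split into 6279 rises and 6537 drops.

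Over both behaviours, HDACi against Veh with 6 libraries each, the pattern was lower promoters and higher primed enhancers. Strong-promoter peaks had a median change of −0.26 with 109 rises and 4220 drops, and primed-enhancer peaks 0.08 with 2345 rises and 409 drops. Active-enhancer peaks had 1276 rises and 2089 drops. The 10 named rises all lay outside promoters, and included intronic peaks of Kcnip4, a partner of Kv4 channels (1.07 ± 0.17), Chn1 (1.03 ± 0.12), Slc7a14 (1.00 ± 0.10) and Ephb2, a receptor of ephrins at synapses (0.97 ± 0.13). The drops included the promoter peaks of Peg3 (−1.63 ± 0.13), Armcx1 (−1.42 ± 0.14) and Fbxw5, a ubiquitin ligase subunit (−1.31 ± 0.15), and of Rpl10 (−1.27 ± 0.10), whose reads may be shared with its many pseudogenes (SE, n = 6 per group). Per library, the mean log2 level of promoter peaks minus that of other peaks was 0.46 ± 0.29 with the drug and 0.65 ± 0.17 with vehicle (SD, n = 6 each; exact permutation p = 0.20), and permuting within behaviours, as added later, gave p = 0.02 with adjusted p = 0.05 (exact permutation). In all, 5065 peaks rose and 8372 fell.

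By list, 11 of 50 cAMP, calcium and MAP kinase promoters rose over both behaviours and 6 fell, 14 and 9 adjusted over the list alone (median 0.03 against −0.20 for all promoters, adjusted p = 0.00021; adjusted p = 0.20 with an estimated correlation). Calm2 rose (0.64 ± 0.08), as did Rasgrf1, an exchange factor for Ras (0.47 ± 0.08), and Prkar1a, a regulatory subunit of protein kinase A, fell (−0.69 ± 0.09). Voltage-gated channels had 4 rises and 4 drops of 41, the same numbers adjusted over the list alone (median −0.02, adjusted p = 0.015; adjusted p = 0.37 with an estimated correlation). Late response genes had 3 rises and 1 drop of 32, the same adjusted over the list alone (median −0.03, adjusted p = 0.017; adjusted p = 0.37 with an estimated correlation), a call lost without Veh-Context replicate 1 (0.052). These medians and that of matrix genes were negative, and the lists passed because other promoters fell further. Extracellular matrix genes had 0 rises and 3 drops of 30, the same adjusted over the list alone (median −0.02, adjusted p = 0.043; adjusted p = 0.37 with an estimated correlation, 0.051 with library totals and 0.0502 with a replicate block). The matrix call was also lost without Veh-Context replicates 1 and 3 (0.057 and 0.062), Veh-CFC replicates 2 and 3 (0.12 and 0.056), HDACi-Context replicates 1 and 3 (0.062 and 0.071) and HDACi-CFC replicate 1 (0.055). Among the deacetylases that CI-994 targets, Hdac3 fell (−0.65 ± 0.11, adjusted p = 2.9e-05), while Hdac1 had a change of −0.19 ± 0.10 and Hdac2 of 0.38 ± 0.14 without passing. By the deposited annotation all 3 of these peaks are intronic, though that of Hdac3 also spans its TSS. Hdac3 had no other promoter peak, and the peaks at the TSS of Hdac1 (0.04 ± 0.19) and Hdac2 (−0.32 ± 0.22) did not pass either. Of all 20 deacetylase-list genes 1 rose and 4 fell, 3 and 6 adjusted over the list alone (median −0.09). Fos rose over both behaviours (0.63 ± 0.13, adjusted p = 0.00074). Of the 28 immediate early genes, however, 4 were higher and 7 lower at an unadjusted p under 0.05 by edgeR's test, and camera did not call that list (adjusted p = 0.16). Microglia markers had a median of −0.42, with 4 of 12 lower (6 adjusted over the list alone), oligodendrocyte markers −0.39, with 2 of 15 lower (6), and housekeeping genes −0.35, with 9 of 19 lower and 1 higher (11 and 2), and camera called none of these 3 lists (adjusted p = 0.36, 0.58 and 0.44).

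**Figure D2:**
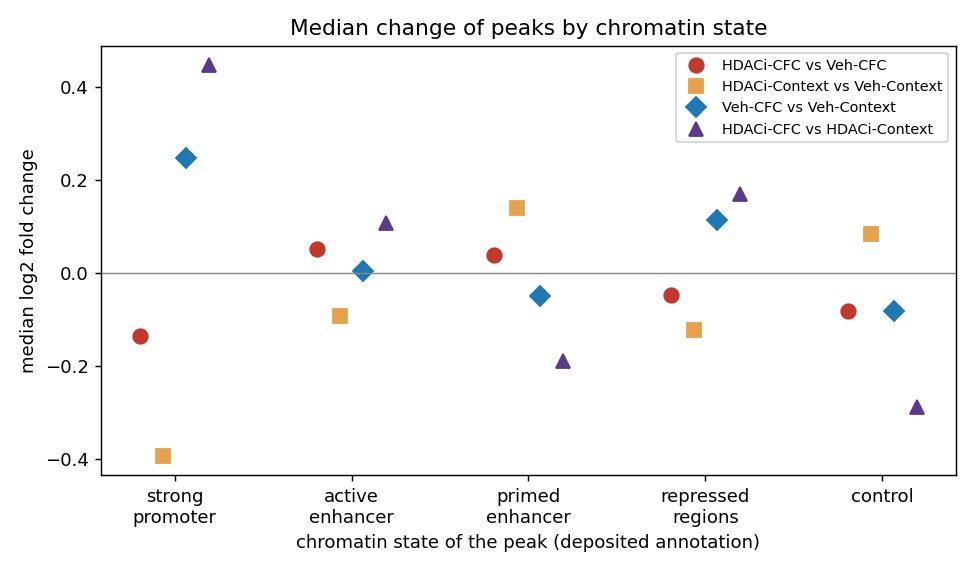
Median log2 fold change of H3K27ac (y axis) over all tested peaks of each deposited chromatin state (x axis) in 4 comparisons of 3 libraries with 3, shown by symbol. Strong promoters sit at −0.14 and −0.39 in the drug comparisons and at 0.25 and 0.45 in the shock comparisons.

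The drug effects in CFC and in Context mice, which share no library, were compared across peaks, which are not independent replicates. Their log2 changes had Pearson r = 0.18 (jackknife SE 0.21 over the 12 libraries; Spearman rho = 0.20; covariance 0.028). Of peaks called in both, 298 rose in both where independent lists would share 19.0, 488 fell in both where 36.6 would be shared, and 1 went opposite ways. The shock effects under vehicle and under the drug, which also share no library, had r = 0.72 (rho = 0.69), with 5722 peaks higher in both (1283 for independent lists), 3068 lower in both (701) and 0 opposite by edgeR.

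The shock effect without the drug, Veh-CFC against Veh-Context, went the other way at promoters, though cage and shock coincide. Strong-promoter peaks had 1960 rises and 83 drops, with a median of 0.25. Promoters rose at Mamld1 (2.48 ± 0.34), Mxi1, an antagonist of MYC (1.81 ± 0.32), Per1 of the circadian clock (0.64 ± 0.12), and Dlg3, a scaffold of the postsynaptic density (0.80 ± 0.14; SE, n = 3 per group). Peaks between genes had 589 rises and 2225 drops, while intronic peaks had 4098 and 1597. Single drops included an intronic peak of the synaptic adhesion gene Nlgn1 (−1.31 ± 0.24) and one near the potassium channel gene Kcnj3 (−1.30 ± 0.27). In all, 6354 peaks rose and 3946 fell.

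Of 45 glutamate receptor and postsynaptic density promoters 20 rose and none fell, 28 adjusted over the list alone, with a median of 0.37 against 0.26 for all promoters (adjusted p = 0.048; adjusted p = 0.84 with an estimated correlation). Leaving out 1 library ended the call in 8 of 12 fits, namely without Veh-Context replicates 1, 2 and 3 (adjusted p = 0.093, 0.069 and 0.067), Veh-CFC replicates 2 and 3 (0.10 and 0.13), HDACi-Context replicate 2 (0.064) and HDACi-CFC replicates 2 and 3 (0.055 and 0.066). The list also did not pass with library totals (adjusted p = 0.054) or with the replicate block (0.073), and turned direction to lower with all peaks within 50 kb (adjusted p = 0.23). Of 28 immediate early genes 8 rose, 12 adjusted over the list alone (median 0.42, adjusted p = 0.36). Among them Nr4a2 rose (1.21 ± 0.24), and its call was lost without Veh-CFC replicate 1. Fos (0.58 ± 0.20), Arc (0.59 ± 0.26), Egr1 (0.24 ± 0.12), Nr4a1 (0.41 ± 0.20), Npas4 (0.01 ± 0.12) and Bdnf (−0.26 ± 0.12) did not pass, while a second Egr1 promoter peak did (0.82 ± 0.23, adjusted p = 0.029) and those of Fos (0.82 ± 0.33) and Npas4 (0.64 ± 0.23) did not. Hdac3 rose (0.55 ± 0.15), a call lost with gene-density offsets and without Veh-CFC replicate 2 or Veh-Context replicate 1, while Hdac1 (0.31 ± 0.15) and Hdac2 (−0.05 ± 0.22) did not pass. Microglia markers had a median of 0.78, with 5 of 12 higher (9 adjusted over the list alone), and oligodendrocyte markers 0.54, with 7 of 15 higher (10).

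The count of 10300 called peaks was 1895 and 6110 without Veh-Context replicates 1 and 2, and 1453 and 6700 without Veh-CFC replicates 1 and 2. It was 6032 by DESeq2 and 6128 with gene-density offsets, which were added later and split it into 4363 rises and 1765 drops, and library totals gave 5364 rises and 5547 drops.

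Under the drug, HDACi-CFC against HDACi-Context, the shock contrast had 29069 rises and 25571 drops. Immediate early promoters rose nearly as a group: 24 of 28 rose and 2 fell, 25 and 2 adjusted over the list alone. Nr4a2 rose by 3.15 ± 0.25, Nr4a1 by 1.49 ± 0.19, Arc, whose product acts at dendritic synapses, by 1.34 ± 0.25, Egr1 by 0.76 ± 0.12, Fos by 0.63 ± 0.16 and Npas4 by 0.49 ± 0.12 on the log2 scale (SE, n = 3 per group). Egr1 went from 46.5 ± 7.28 CPM in HDACi-Context to 78.9 ± 4.30 CPM in HDACi-CFC, and Arc from 18.3 ± 5.25 to 46.4 ± 3.94 CPM (SD, n = 3). The Npas4 change turned to −0.14 with gene-density offsets, and Bdnf had a change of −0.26 ± 0.12 without passing. Second promoter peaks rose by 2.02 ± 0.21 at Egr1, 1.34 ± 0.22 at Npas4, 1.44 ± 0.19 at Arc and 0.59 ± 0.12 at Bdnf. Glutamate receptor and postsynaptic density promoters rose in 35 of 45 cases, the same number adjusted over the list alone, and Psd (1.56 ± 0.14) and Camk2b, a subunit of calcium/calmodulin kinase II (1.26 ± 0.12), were examples.

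The list medians of the drug-treated shock contrast were 0.86 for immediate early genes (adjusted p = 0.029; adjusted p = 0.67 with an estimated correlation) and 0.73 for glutamate genes (adjusted p = 0.0034; adjusted p = 0.67 with an estimated correlation), against 0.44 for all promoters. The first call was lost without Veh-Context replicate 2 (adjusted p = 0.051), and the second turned to lower with all peaks within 50 kb (adjusted p = 0.33). Other promoters that rose included Mamld1 (4.31 ± 0.40) and the deacetylase genes Hdac3 (1.25 ± 0.15) and Hdac1 (0.65 ± 0.14), the latter lost with gene-density offsets, while Hdac2 had a change of −0.08 ± 0.19. The named peaks that fell lay away from promoters, as near Grin2a, an NMDA receptor subunit (−1.57 ± 0.20), and Gpm6a, a neuronal membrane glycoprotein (−1.60 ± 0.25). Microglia markers had a median of 1.42, with 10 of 12 higher and 1 lower, and oligodendrocyte markers 1.11, with 12 of 15 higher, the same adjusted over the list alone. Library totals moved the median of all peaks from −0.05 to −0.18 and the split to 23366 rises and 37912 drops, and gene-density offsets gave 26866 and 14206. With loess offsets the glucocorticoid-induced gene Zbtb16 turned from 0.68 ± 0.09 to −0.18.

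**Figure D3:**
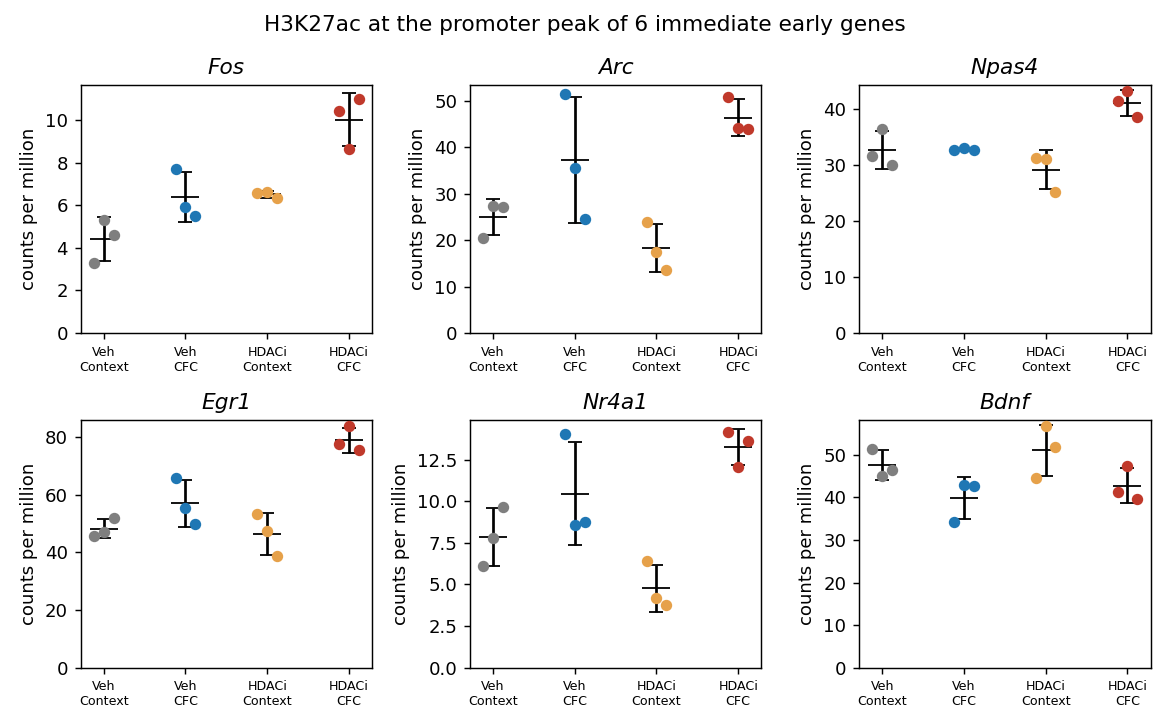
H3K27ac in CPM (y axis) at the promoter peak of 6 genes in the 4 groups (x axis). The peaks of Egr1, Arc and Npas4 are intergenic active enhancers by the deposited annotation and stop short of the TSS. Those of Fos and Nr4a1, strong promoters by state, stop short of it too. Points are the 3 libraries of a group, horizontal lines their mean and bars 1 SD; Arc, Egr1, Nr4a1, Npas4 and Fos had higher values in each HDACi-CFC library than in each HDACi-Context library.

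Over both drugs, CFC against Context with 6 libraries each, 30813 peaks rose and 28330 fell, and most lists rose as part of a general rise of promoters, whose median was 0.35. Glutamate receptor and postsynaptic density promoters rose in 38 of 45 cases, 39 adjusted over the list alone (median 0.58), and camera called no other list (adjusted p = 0.0067; adjusted p = 0.71 with an estimated correlation, and lower direction with all peaks within 50 kb, adjusted p = 0.17). Psd (1.14 ± 0.10) was an example (SE, n = 6 per group). Of 28 immediate early genes 24 rose and 2 fell, 25 and 2 adjusted over the list alone (median 0.63, adjusted p = 0.072), including Nr4a2 (2.18 ± 0.18), Arc (0.96 ± 0.18), Nr4a1 (0.95 ± 0.14), Fos (0.60 ± 0.13) and Egr1 (0.50 ± 0.08). Bdnf, a neurotrophin gene, fell (−0.26 ± 0.08, adjusted p = 0.012), with adjusted p = 0.41 under gene-density offsets and 0.054 without HDACi-Context replicate 2, whereas another of its promoter peaks rose (0.38 ± 0.09, adjusted p = 0.00052). Npas4 had 0.25 ± 0.08 and turned to −0.25 with gene-density offsets. Its call was also lost with library totals and loess offsets and without HDACi-Context replicate 3, at adjusted p-values of 0.081, 0.18 and 0.054, while its second promoter peak rose by 0.99 ± 0.16.

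Members of other lists rose too, as did 10398 of all 21487 promoter peaks (48.4%), and none of the lists in this paragraph passed camera (adjusted p = 0.36 to 0.66). That share includes weaker promoter peaks, whereas a list holds only the peak with the highest mean count of each gene. It is thus not a matched baseline for the counts below. Late response genes had 20 of 32 members higher and 1 lower (the same adjusted over the list alone), among them the neuritin gene Nrn1 (0.78 ± 0.07). Presynaptic release had 19 of 36 higher (21 adjusted over the list alone). Voltage-gated channels had 29 of 41 higher and 1 lower (30 and 1), cell adhesion and axon guidance 24 of 42 (25), with Nrp2 of semaphorin signalling (1.07 ± 0.10), and cAMP, calcium and MAP kinase signalling 28 of 50 (29). Neuropeptides and growth factors had 16 of 30 higher (16), extracellular matrix 19 of 30 (19), GABA receptors 6 of 14 (6), deacetylases 13 of 20 (13) with Hdac3 (0.90 ± 0.11), acetyltransferases and readers 12 of 16 (13), glucocorticoid response genes 15 of 22 (16) and housekeeping genes 13 of 19 (14), each count in brackets adjusted over the list alone. GABA receptors had the lowest median, 0.12, with camera's direction down.

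Marker promoters of other cell types moved with the shock too. Microglia markers had 10 of 12 higher (10 adjusted over the list alone) and a median of 1.15, with Spi1, a myeloid transcription factor, at 1.65 ± 0.24. Oligodendrocyte markers had 13 of 15 higher (13) and a median of 0.82, with the myelin gene Mag at 1.72 ± 0.18. Astrocyte markers had 10 of 14 higher (11) and a median of 0.33, oligodendrocyte precursors 4 of 7 (4) and 0.46, and endothelial and mural cells 2 of 6 (2) and 0.39. Granule neuron markers had 16 of 25 higher and 2 lower (17 and 2) and a median of 0.39, with Prox1, which marks granule cells, at 0.79 ± 0.08. CA pyramidal markers had 11 of 15 higher and 1 lower (11 and 1) and a median of 0.58, and interneuron markers 6 of 10 higher and 1 lower (6 and 1) and 0.31. None of these 8 lists passed camera against other promoters in this contrast, 0 at an unadjusted p under 0.05, while fry called 8.

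Outside promoters, the shock effect followed how many genes lay nearby. In the class of peaks with 0 to 3 protein-coding genes within 500 kb the median change was −0.28 under vehicle and −0.48 under the drug, and with 26 to 73 genes it was 0.33 and 0.50. The slope of log2 level on gene density was −0.022 ± 0.045 in CFC and −0.215 ± 0.068 in Context libraries (SD, n = 6 each), higher in 6 of 6 libraries (exact permutation p = 0.0022, the smallest possible; adjusted p = 0.026). By group the slope was −0.025 ± 0.071 in Veh-CFC, −0.172 ± 0.027 in Veh-Context, −0.018 ± 0.005 in HDACi-CFC and −0.259 ± 0.070 in HDACi-Context (SD, n = 3 each). Replicates of Veh-CFC and of HDACi-Context thus also spread along this trend, beside a shock difference of 0.146 under vehicle. The median drug effects in the lowest and highest classes of gene density were 0.15 and −0.21 in Context mice, and −0.03 and −0.01 in CFC mice. With library totals the pooled shock contrast split into 25908 rises and 38010 drops, and with gene-density offsets into 28153 and 17054.

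**Figure D4:**
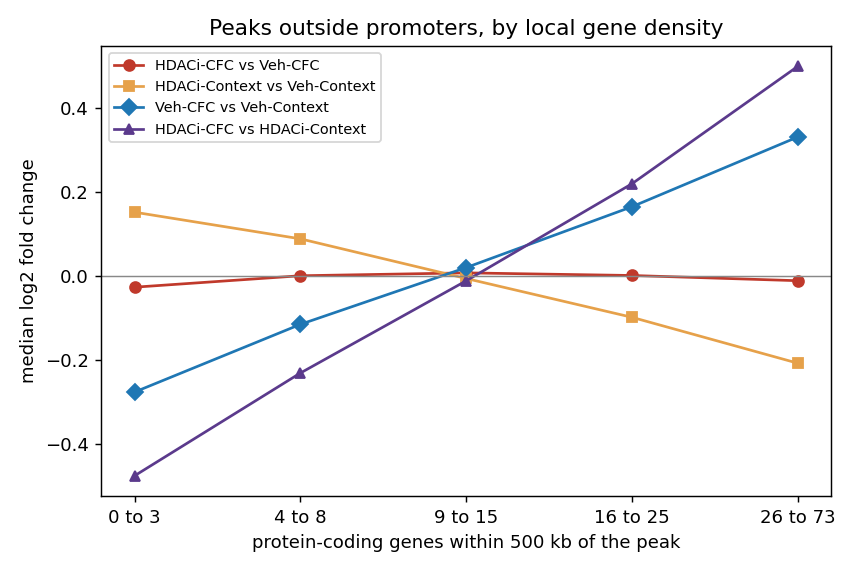
Median log2 fold change of H3K27ac (y axis) of peaks outside promoters in 5 classes of the number of protein-coding genes within 500 kb (x axis), for 4 comparisons. The shock comparisons run from −0.28 and −0.48 at 0 to 3 genes to 0.33 and 0.50 at 26 to 73 genes.

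Whether the drug acted differently after shock was tested by the interaction, the drug effect in CFC minus that in Context. By edgeR 49 peaks had a positive and 1 a negative interaction, of 16531 at an unadjusted p under 0.05. The largest was the promoter peak of Nr4a2, an orphan nuclear receptor of the immediate early response (1.95 ± 0.37, adjusted p = 0.037). Peaks at Kcnj4, an inward rectifier channel (1.31 ± 0.26), Eno2, the neuronal enolase (1.21 ± 0.25), Anp32a, a histone-binding protein that inhibits acetylation (1.64 ± 0.32), and Naa38 (1.32 ± 0.20) followed, and the negative one lay near the chemokine gene Xcl1 (−1.68 ± 0.35; SE, n = 3 per group). Of 28 immediate early genes 1 had a positive interaction over all peaks and 12 adjusted over the list alone (median 0.51 against 0.21 for all promoters, adjusted p = 0.030; adjusted p = 0.75 with an estimated correlation). Among them Nr4a1 (1.08 ± 0.28), Arc (0.76 ± 0.36), Egr1 (0.52 ± 0.17), Npas4 (0.48 ± 0.17), Fos (0.05 ± 0.26) and Bdnf (−0.0012 ± 0.17) did not pass over all peaks. Of 45 glutamate genes 1 passed and 13 did so adjusted over the list alone (median 0.32, adjusted p = 0.030; adjusted p = 0.75 with an estimated correlation). Markers of other cell types had medians as high without passing camera: 0.62 over 6 genes of endothelial and mural cells, 0.56 over 15 of oligodendrocytes, 0.53 over 7 of their precursors and 0.41 over 12 of microglia (adjusted p = 0.36, 0.65, 0.91 and 0.91).

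This count rested on the settings: it was 1 with library totals or loess offsets, 6 with a minimum count of 30 and 995 by DESeq2. Without 1 library it was 874, 2 and 0 for Veh-Context replicates 1, 2 and 3, 2588, 1 and 1 for those of Veh-CFC, 3731, 1 and 1 for those of HDACi-Context and 9, 2 and 1 for those of HDACi-CFC. The 0 by edgeR stood beside 11655 peaks at an unadjusted p under 0.05. None of the 11 named peaks stayed past the threshold whichever library was left out.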

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

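The count of other splits below was chosen only after the result was seen. The drug effect differed between CFC and Context mice at 50 peaks in the test of the difference itself. In that test the promoters of immediate early genes had a median of 0.51 (0.50902) over 28 genes, and those of glutamate receptors and the postsynaptic density 0.32 (0.321648) over 45 genes, against 0.21 for all promoters. Markers of endothelial and mural cells (0.62 over 6 genes) and of oligodendrocytes (0.56 over 15) had medians higher still without passing camera. Both lists passed camera with the preset correlation and neither did with an estimated one (adjusted p = 0.75 for both). Of 60 splits of the 12 libraries, drawn at random among those that kept 3 drug and 3 vehicle labels in each behaviour, 8 called as many peaks, and the highest other called 4140, so chance was not excluded. For lists, 20 of the 60 splits called as many as the 2 seen, with up to 5 in another split. Of the 7 other splits that called as many, 5 exchanged unequal numbers of drug labels in the 2 behaviours, which carries the drug effect itself into the difference. The other 2 did not, and called up to 1738, which points to a structure of the samples whose source was not tested, and leaving out HDACi-Context replicate 1 or Veh-CFC replicate 1 raised the count to 3731 and 2588. No biological explanation of the difference was tested.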

How the results depend on the processing

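Of the alternatives below, gene-density offsets and the residual factor (the first component of the residuals as a covariate) were chosen only after the results were seen. A count of peaks within 1.5 times that reported was called the same. This held for the pooled CFC against Context contrast in 22 of 22 alternatives (39472 to 65977 peaks), HDACi-CFC against HDACi-Context in 22 of 23, HDACi against Veh over both behaviours in 20 of 22, HDACi-Context against Veh-Context in 18 of 23, Veh-CFC against Veh-Context in 15 of 23, HDACi-CFC against Veh-CFC in 14 of 23 and the interaction in 1 of 22.

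With an adjusted p under 0.01, a stricter threshold by construction, the counts were 324 for HDACi-CFC against Veh-CFC, 5456 for HDACi-Context against Veh-Context, 2203 for Veh-CFC against Veh-Context, 33867 for HDACi-CFC against HDACi-Context, 6776 for HDACi against Veh and 1 for the interaction. For the other changes, apart from those with the residual factor, the cause was not tested. DESeq2 gave 6032 for Veh-CFC against Veh-Context and 995 for the interaction. The interaction had 1 peak with library totals, 100 with RLE factors, 1 with loess offsets, 6 with a minimum count of 30, 89 with the replicate block, 552 with gene-density offsets and 5704 with the residual factor. Gene-density offsets gave 2123 for HDACi-CFC against Veh-CFC and 6128 for Veh-CFC against Veh-Context. The residual factor gave 5751 for HDACi-CFC against Veh-CFC, 23239 for HDACi-Context against Veh-Context, 19370 for Veh-CFC against Veh-Context and 20638 for HDACi against Veh. That covariate was taken from the residuals of these same counts, so it lowers the spread between replicates by construction. Its higher counts, that of the interaction included, are therefore no independent support.

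Leaving out 1 library gave 225 to 2610 peaks for HDACi-CFC against Veh-CFC (lowest without HDACi-CFC replicate 3, highest without Veh-CFC replicate 1) and 4630 to 17531 for HDACi-Context against Veh-Context (without Veh-Context replicate 3, HDACi-Context replicate 1). For Veh-CFC against Veh-Context it gave 1453 to 14548 (without Veh-CFC replicates 1 and 3), and for the interaction 0 to 3731 (without Veh-Context replicate 3, HDACi-Context replicate 1). For the total count, HDACi minus Veh ranged from 3.10e+06 to 4.55e+06 counts, and its unadjusted p (0.039 with all libraries, adjusted p = 0.17, so not passed; exact permutation) was above 0.05 in 8 of 12 such fits.

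No list passed with an estimated correlation: 0 in each of the 6 contrasts other than the interaction, with 4, 1, 0, 0, 1 and 0 lists at an unadjusted p under 0.05. In the same order, HDACi against Veh being the fifth, fry called 1, 20, 20, 22, 3 and 22 of the 22 lists, and 15 for the interaction. Its calls do not tell a list from a general shift of promoters. With all peaks within 50 kb, 10, 6, 9, 11 and 6 lists passed for HDACi-Context against Veh-Context, Veh-CFC against Veh-Context, HDACi-CFC against HDACi-Context, HDACi against Veh and CFC against Context. For Veh-CFC against Veh-Context 0 passed with library totals and 0 with the replicate block. Leaving out 1 library gave 0 to 1 lists for HDACi-Context against Veh-Context, 0 to 1 for Veh-CFC against Veh-Context, 1 to 2 for HDACi-CFC against HDACi-Context, 2 to 5 for HDACi against Veh and 1 to 2 for CFC against Context.

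The median drug change of promoter peaks minus that of other peaks, −0.20 over both behaviours, was −0.16 with gene-density offsets and ranged from −0.22 to −0.16. Its test on values per library passed in none of these 17 alternatives (exact permutation p = 0.11 with those offsets, against 0.20 as reported), and the residual factor was not run for it. That test permuted drug labels over both behaviours together, so the shock difference added to its spread. The test within behaviours was not repeated over the alternatives. The correlation of the drug effects ranged from 0.0070 to 0.28 over 17 alternatives. Zbtb16 turned to −0.18 with loess offsets in HDACi-CFC against HDACi-Context, and with gene-density offsets Npas4 turned to −0.14 there and to −0.25 in CFC against Context, and Matn4 to −0.054 in the latter. Of the named peaks past the threshold, those that were lost in no alternative that gave them an adjusted p, the threshold of 0.01 not being applied to them, numbered 12 of 38 for HDACi-CFC against Veh-CFC, 51 of 83 for HDACi-Context against Veh-Context, 33 of 76 for Veh-CFC against Veh-Context, 81 of 90 for HDACi-CFC against HDACi-Context, 65 of 77 for HDACi against Veh, 85 of 92 for CFC against Context and 0 of 11 for the interaction. DESeq2 gave an adjusted p to 23, 79, 74, 90, 74, 92 and 2 of them, and a minimum count of 30 to 38, 81, 74, 89, 75, 91 and 11. The input results and subtraction of input were not run, since no column belonged to an input sample. At this depth, group size and spread many changes would be missed where few peaks change. In counts simulated for HDACi-CFC against Veh-CFC, 15% of the 100 peaks changed 1.5-fold were recovered, among 29894 tested. That share does not carry over to contrasts with many changed peaks, such as CFC against Context over both drugs, where 41.1% were called.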

Other observations

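Each test in this part was chosen only after its result was seen, except the comparison of glial marker promoters with random lists of matched read density.

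For the rise of gene-dense regions and promoters after shock, weighed first, offsets on gene density were fitted outside promoters. With them the median of promoter peaks was 0.26, against 0.33 without (larger SD between libraries of a behaviour 0.145). This argues against a bias that follows gene density as the whole cause at promoters. Outside them the offsets remove the trend by construction and leave such a bias open. GC content of peaks was not computed, and gene density was used in its place, so a bias that follows GC content stays open at promoters too. Promoter peaks in the highest of 5 classes of read density still rose by a median of 0.25, with a mean log2 level per library of 3.33 ± 0.095 in CFC and 3.04 ± 0.218 in Context (SD, n = 6 each; exact permutation p = 0.017), which argues against more unenriched background in CFC libraries as the whole source at those peaks. At other peaks the highest class changed by −0.17 and the lowest by 0.32, and per library the log2 level of low minus high read density (−2.47 in CFC, −2.91 in Context) and the satellite-like peak were higher in CFC (exact permutation p = 0.0043, adjusted p = 0.030 for each), so more background in CFC libraries may account for part of the change. In 1 of 60 splits, the real one, as many peaks as the 59143 reported were called (highest other 2676), which argues against chance, but shock and cage coincide, so a cage effect and an effect of learning both stay open.

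For the lower promoters and higher primed enhancers under CI-994, weighed next, the median of strong-promoter peaks was −0.251 with gene-density offsets, near the −0.26 reported. This argues against a gene-density bias as the whole cause, while a bias that follows GC content was not tested here either. With library totals it was −0.249, but the mean log2 scaling factors of drug and vehicle libraries differed by 0.0134, too little to bring it to 0, and without a spike-in or input a general gain of the mark and a loss at promoters cannot be told apart, whereas 1 factor per library leaves the gap between strong promoters (−0.26) and primed enhancers (0.08) as it is. In 1 of 60 splits, the real one, as many peaks were called (13437, with 4713 in the highest other), which argues against chance for that count alone: the level of promoter minus other peaks per library gave p = 0.20, and p = 0.02 within behaviours with adjusted p = 0.05, which did not pass (exact permutation). The log2 level of low minus high read density differed by −0.000522 between drug and vehicle libraries (permutation p = 0.99 within behaviours). Their SD of 0.305 holds the shock difference of 0.447, but the 3 Veh-CFC libraries alone had an SD of 0.315. This spread is too wide to decide on more background with the drug. The satellite-like peak, lower with the drug by 53.9 CPM (permutation p = 0.005 within behaviours, adjusted p = 0.04), goes against more background but is 1 peak, so this stays open. Active enhancers had 1276 rises and 2089 drops, and an effect of the inhibitor stays open and was not tested separately.

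Marker promoters of microglia and oligodendrocytes rose after shock by a median of 0.86 over 27 genes, though nuclei were sorted for NeuN, which should remove both. Astrocyte markers had a median of 0.33 over 14 genes against 0.35 for all promoters, below the microglia and oligodendrocyte lists by a mean of 0.52. The SE of 0.149 was taken over genes, which are not independent replicates. The lists were not matched on read density, and those of microglia and oligodendrocytes were the cell type lists with the highest medians. This gap therefore cannot decide on more nuclei of other cell types in the CFC libraries. Among 10000 random promoter lists matched on read density the median stood at percentile 70.3, inside their central 95% range of 0.53 to 1.04. The low read density of these promoters may thus explain the rise at promoters. Outside promoters, peaks named for oligodendrocyte markers rose by a median of 0.45 (66 of 133 higher, 6 lower). Those of their precursors rose by 0.41 (18 of 36 higher, 2 lower). In the other cell type lists this median ran from −0.16 (granule neurons) to 0.19 (microglia). Read density was not matched for these peaks, and a difference in oligodendrocyte nuclei alone was not tested, so both stay open. Among the markers with the highest levels, Mbp had 96.6 ± 6.40 CPM in Veh-Context and 124 ± 7.58 CPM in Veh-CFC, and 72.1 ± 3.16 in HDACi-Context and 124 ± 10.1 in HDACi-CFC (SD, n = 3), and P2ry12 19.0 ± 2.85, 19.9 ± 1.39, 19.1 ± 2.01 and 15.0 ± 1.89 CPM in the same order, beside medians of the microglia and oligodendrocyte lists of 0.78 and 0.54 under vehicle and 1.42 and 1.11 under the drug. How many of these genes sorted neurons also mark with H3K27ac was not tested.

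For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split called 1322 peaks for HDACi-CFC against Veh-CFC (highest other 0), 12357 for HDACi-Context against Veh-Context (487), 10300 for Veh-CFC against Veh-Context (0) and 54640 for HDACi-CFC against HDACi-Context (0), and 1 of the 10 splits, the real one, reached that count in each. Lists numbered 6 (highest other 7, reached by 3 of 10 splits), 1 (1, 3 of 10), 1 (2, 5 of 10) and 2 (1, 1 of 10) in the same order. Over both behaviours the 4 lists of the drug effect were reached by 10 of 60 splits (highest other 8), and over both drugs the 1 list of the shock effect by 23 of 60 (2), so chance was not excluded for these list counts.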
